A study of Mus musculus with 12 samples.

How the data were processed

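RNA was measured by bulk RNA sequencing of haematopoietic stem and progenitor cells (HSPCs), sorted from fresh mouse bone marrow as cells negative for lineage markers and positive for the receptor cKit, per the labels. The cells came from mice given vehicle (VEH) or metformin (MET) for 1 month in a competition experiment. Metformin is a biguanide drug that inhibits respiratory complex I. Wild-type (WT) cells were Dnmt3a+/+ and mutant (RH) cells carried 1 allele of Dnmt3a with the change R878H, both on a C57BL/6 background with the interferon-inducible Mx1-cre transgene. Dnmt3a encodes a de novo DNA methyltransferase. The 4 groups, WT VEH, WT MET, RH VEH and RH MET, held 3 libraries each. Per the labels' protocols, RNA was extracted with a column kit, libraries were made with NEBNext Ultra RNA reagents and sequenced as 150-base paired reads on a NovaSeq instrument.

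Raw read counts per gene, whole numbers with no normalization, were deposited by the authors for 54532 mouse gene IDs. STAR 2.5, HTSeq 0.6.1 and the build mm10 are named, with no order or settings, per the submitters' processing notes; how reads that map to several places and strand were handled is not given in the sources used here. Near-identical copies, pseudogenes and overlapping genes can share or lose reads under some settings. This was not tested here, and it is a limit for genes with many copies, such as ribosomal protein genes and Gapdh. Total counts per library ran from 13359583 to 21938003. With the TMM factors, 1 CPM stood for 8.37 reads in RH VEH 2, 9.86 in WT MET 2 and 17 to 24.8 in the other 10 libraries, so counting error alone is large for genes below that level; intervals given for counts cover counting error only. No line of the tables lacked a gene name.

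Counts came from a table of 12 libraries. A smaller table of 8 columns held 6 of the same columns with unchanged counts, and its other 2 columns matched no sample of the series and were not used here. The 6 libraries found in both tables are called round 1 (WT VEH 1 and 2, WT MET 1, RH VEH 1, RH MET 1 and 2), and the 6 found only in the table of 12 are called round 2 (WT VEH 3, WT MET 2 and 3, RH VEH 2 and 3, RH MET 3). This split matches the labels, which give a library name to 6 samples only, and it crosses all 4 groups. Library numbers are those of the columns of the table of 12. Some of them differ from the numbers in the labels, so for 6 columns the group is known and the exact sample is not. Gene names and coordinates are those of the deposited table; 54409 of its IDs are in GENCODE release M21 of the mouse and 53499 have the same start and end there.

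The main test was edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3 on the counts as deposited, with TMM normalization, the filterByExpr filter (15003 genes kept) and a model with a mean per group plus a round term over all 12 libraries. A gene was called at a Benjamini-Hochberg adjusted p (over all genes tested, per comparison) under 0.05. The 7 comparisons were RH against WT under vehicle and under metformin, metformin against vehicle in RH and in WT, the difference between these metformin effects, and the mean genotype and mean metformin effects. Levels are TMM-normalised CPM. The biological coefficient of variation was 0.256.

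Before the data were examined, the design, the alternatives, the rule for named genes and 35 gene lists were fixed, of which 34 had at least 5 tested members. They covered respiratory complex I, complexes II to V, the mitochondrial genome, glycolysis, TCA cycle, the one-carbon and methionine cycle, the DNA methylation machinery, PRC2, homeobox and Meis genes, the ATF4 stress response, cholesterol synthesis, fatty acid oxidation, cytosolic and mitochondrial ribosomes, S phase, mitosis, p53 targets, interferon, NF-kB and TNF, immediate early, hypoxia, NRF2 and lysosome genes. Cell type lists covered stem, multipotent progenitor, granulocyte, monocyte, dendritic, erythroid, megakaryocyte, mast, B, T and NK, and stromal and endothelial genes. The list of 6 sex-linked genes had too few tested members; Xist held 8054 to 19735 counts and Ddx3y, Kdm5d and Uty held 0 counts in all 12 libraries. Lists overlap: 12 of the 35 tested stem cell genes, 6 of the 16 multipotent progenitor genes and 5 of the 27 megakaryocyte genes are also in another list. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the 34 lists of a comparison. Camera with an estimated correlation and fry were the alternatives.

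The named genes were fixed by rule. Genes past the threshold with a mean log2 CPM of at least 1, the same sign in separate fits of both rounds and a symbol that is not a clone, pseudogene, histone or receptor segment came first, up to 12 per direction. Where fewer than 10 passed, the genes of smallest p under the same filters filled the number to 10, as values only. Of each list, members past the threshold or up to 2 of smallest p were named, and always Dnmt3a, Dnmt3b, Dnmt1, Tet1, Tet2, Tet3, Kit and Ly6a.

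Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter, a filter of 1 CPM in 6 libraries, no round term, the label number as a replicate block, limma voom with a correlation within assumed animals (libraries of the same treatment and label number, and each library without a label number on its own, as the true animals are not known), each round alone, only the groups compared, and leaving out each library. After the data were seen, 3 alternatives were added: leaving out the 2 libraries with over 10% of counts from the mitochondrial genome, an added level of the round term for them, and the shares of counts without them. No pair of libraries of a group was a duplicate: chi-square per degree of freedom ran from 12.51 to 584.9. Whether the label numbers pair libraries across groups could not be decided.

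Correlations of fold changes were taken across genes and set beside 40 simulations of unchanged groups, in which genes were drawn independently. Shares of counts were compared with two-sided exact permutation tests between groups of 3, whose smallest possible p is 0.1. The procedure was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, all of a mean log2 CPM of at least 1. For RH VEH against WT VEH (14727 genes), 46% of 2-fold and 90% of 4-fold changes were recovered; for the mean genotype effect (14763 genes), 79% and 96%. A list shifted by 0.4 (log2) was called there with the preset and with the estimated correlation. Simulated genes were drawn independently, so this does not show how either test handles lists whose members move together. False calls of single genes were 12 of 149 and 10 of 191 in the 2 comparisons.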

Results

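Transcript levels were measured in 12 libraries of sorted Lin-cKit+ bone marrow cells, the compartment of haematopoietic stem and progenitor cells. The cells were wild type (WT) or carried the heterozygous R878H change in the DNA methyltransferase gene Dnmt3a (RH). They came from mice given vehicle (VEH) or metformin (MET) for 1 month in a competition experiment. Each of the 4 groups held 3 libraries, with total counts of 13359583 to 21938003 per library. The study asked how metformin acts on mutant and wild-type progenitors. The labels give 2 animals per treatment group and tie no library to an animal, so p-values measure the spread between libraries, which may in part be technical.

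Dnmt3a itself differed between the groups by less than the spread between libraries. It stood at 39.7 to 60 CPM in the 12 libraries, with log2 fold changes of −0.11 ± 0.159 (SE, n = 3 per group) for RH against WT under vehicle and 0.14 ± 0.160 under metformin. Neither passed the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg). The mutation is a heterozygous point change, so this level does not check the genotype labels. Dnmt1, the maintenance methyltransferase, stood at 533 ± 42.2 CPM (SD, n = 3) in WT VEH, 394 ± 51.6 in WT MET, 458 ± 83.7 in RH VEH and 492 ± 30.4 in RH MET. Dnmt3b stood at 26.4 to 27.7 CPM in the 4 group means. The stem and progenitor receptor Kit had group means of 144 to 165 CPM and Ly6a, which encodes Sca-1, of 5.19 to 7.45 CPM. Dnmt1, Dnmt3b, Tet1, Tet2, Tet3, Kit and Ly6a passed the threshold in none of the 7 comparisons.

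The share of counts from the mitochondrial genome set 2 libraries apart. It was 33.3% in WT MET 2 and 40.8% in RH VEH 2, against 2.29% to 4.33% in the other 4 libraries of these groups and 1.57% to 3.02% in the 6 libraries of the other groups. As group values, it was 2.14% ± 0.560 (SD, n = 3) in WT VEH, 13.3% ± 17.4 in WT MET, 15.7% ± 21.8 in RH VEH and 2.59% ± 0.390 in RH MET. In none of the 4 comparisons between single groups was the difference larger than the spread (exact permutation p = 0.2 to 0.3, with 0.1 the smallest possible). As a mean of the 2 libraries, levels of granulocyte genes were lower than in the other 4 libraries of round 2 (median log2 difference −2.07). The same held for monocyte genes (−1.30) and mast cell genes (−1.01). Levels of megakaryocyte genes were higher by the same measure (0.81). The size of the shifts of the mitochondrial genome list rested on these 2 libraries. Without them its median was 0.59 in place of 2.55 for RH against WT under vehicle, −0.42 in place of −2.08 under metformin, −0.32 in place of −2.41 for metformin in RH and 0.68 in place of 2.18 in WT. Both libraries stood at the far end of the first principal component, which held 34.6% of the variance. On the second, with 15.7%, they stood at opposite ends (WT MET 2 at −66.33, RH VEH 2 at 37.32). Haemoglobin genes took 0.268% to 0.751% of counts and cytosolic ribosomal protein genes 5.14% to 8.73% in the 12 libraries. In the same 4 comparisons no difference was larger than the spread (exact permutation p = 0.5 to 1). Without WT MET 2 and RH VEH 2, the share of ribosomal proteins was 6.601% ± 0.212 (SD, 3 libraries) in RH MET and 7.92% ± 0.545 (2 libraries) in WT MET, at an exact permutation p of 0.1, the smallest possible.

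**Figure D1:**
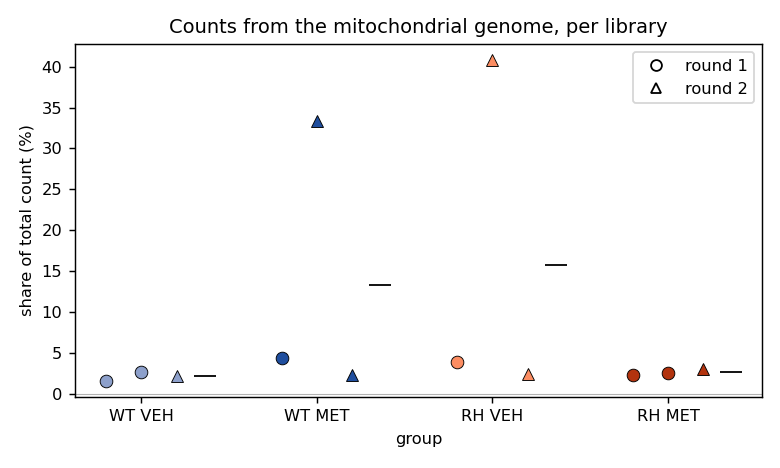
Share of the total count from genes of the mitochondrial genome (y axis, percent) in each of the 12 libraries by group (x axis); circles are round 1, triangles round 2, and short lines the group means. WT MET 2 at 33.3% and RH VEH 2 at 40.8% stand above the other libraries, which lie between 1.57% and 4.33%.

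Slc15a2, which encodes the proton-coupled peptide transporter PEPT2, was the 1 gene past the threshold in any comparison by edgeR with the filter. With no filter, edgeR called 63 to 431 of 27530 genes per comparison, 63 to 412 of them among the 15003 genes that the filter keeps. The gene (ENSMUSG00000022899) lies on chromosome 16 at 36750177 to 36784962 (mm10). Its level was 0.411 ± 0.218 CPM (SD, n = 3) in WT VEH and 0.0537 ± 0.0930 in WT MET, against 9.74 ± 6.32 in RH VEH and 7.83 ± 4.65 in RH MET. Every RH library, with 36 to 339 counts, was above every WT library, with 0 to 12 counts. Over both treatments the ratio of levels was 35.4 (95% interval 24.4 to 53.6, counting error only). The exact permutation p of this gene was 0.00216 for genotype, the smallest of 924 splits, and 0.545 for metformin. The gene was chosen for its separation, and 14 of the 15003 genes parted the genotypes as fully, where chance gives 32.5, so the first p alone does not set it apart.

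**Figure D2:**
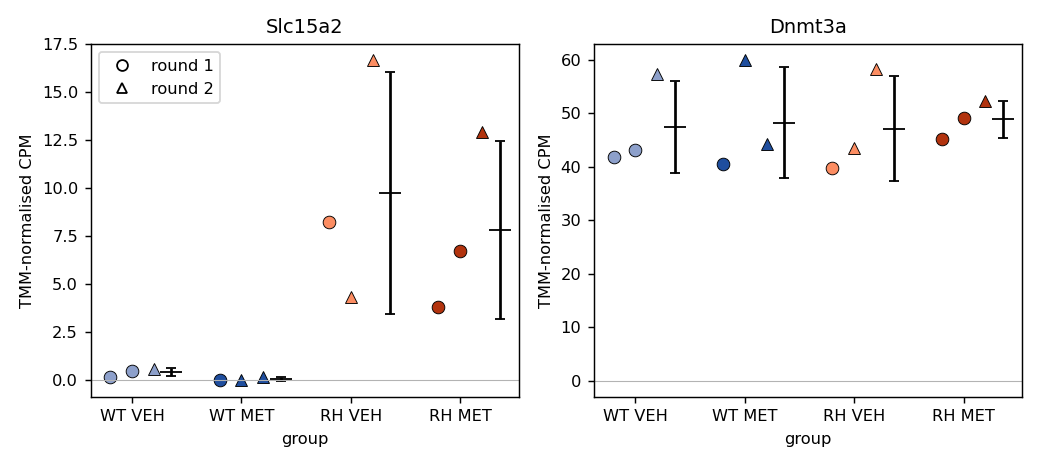
TMM-normalised CPM (y axes) of Slc15a2 and Dnmt3a in each of the 12 libraries by group (x axes); circles are round 1, triangles round 2, and bars the group mean ± SD (n = 3). Slc15a2 lies between 3.82 and 16.7 CPM in RH libraries and at most 0.581 CPM in WT libraries, while Dnmt3a lies between 39.7 and 60 CPM throughout.

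The comparison of RH VEH with WT VEH gives the difference between the genotypes without drug. Genes of respiratory complex I, the first enzyme of the electron transport chain, rose as a list, with 34 of 36 members higher and a median log2 fold change of 0.28 (camera, adjusted p = 3.25e-05; adjusted p = 0.922 with an estimated correlation). Complexes II to V (32 of 39 higher, median 0.22), the mitochondrial genome (12 of 12 higher, median 2.55), the mitochondrial ribosome (36 of 42 higher, median 0.23) and the cytosolic ribosome (40 of 54 higher, median 0.11) rose as well. NF-kB and TNF response genes fell, with 23 of 28 lower and a median of −0.34. Granulocyte genes (26 of 28 lower, median −0.59), monocyte genes (23 of 26 lower, median −0.32) and stromal and endothelial genes (20 of 24 lower, median −0.28) fell too. RH VEH 2 bears on many of these lists. Without it and WT MET 2 the medians were 0.59 for the mitochondrial genome, 0.08 for the mitochondrial and 0.01 for the cytosolic ribosome (the 2 ribosome lists no longer called), 0.13 for complex I and 0.11 for complexes II to V. As a mean, these 2 libraries had low levels of granulocyte (−2.07), monocyte (−1.30) and stromal genes (−0.70) against the other libraries of round 2. Without them those medians were −0.23, 0.05 and −0.05, and in round 1 alone the granulocyte median was 0.01 and the monocyte median 0.13. Without the 2 libraries 5 of the 9 lists called here were called in the same direction, and 4 were not. These 9 lists passed by camera with the preset correlation (adjusted p = 3.25e-05 to 0.00482), each at adjusted p = 0.922 with an estimated correlation. No member of any list passed the threshold over all genes. Adjusted over the list alone, 1 glycolysis gene passed.

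That gene was Gapdh, a glycolytic enzyme whose many pseudogenes can make its counts uncertain, at log2 fold change 2.68 ± 0.545 (SE). It stood at 172 CPM in RH VEH 1 and 68.1 in RH VEH 3, but at 18.3 in RH VEH 2 and 13.2 to 14.4 in the WT VEH libraries. Slc15a2 was at 4.32 ± 0.632 with adjusted p = 0.24 by the edgeR quasi-likelihood test. Its ratio of levels was 26.4 (95% interval 17.7 to 41.1, counting error only). Other genes of smallest p were the zinc finger gene Zbtb10 (−1.14 ± 0.289), the receptor gene Erbb3 (−1.26 ± 0.351), Sdc2 (−1.02 ± 0.300) and the NF-kB subunit gene Nfkb2 (−0.69 ± 0.207), all with negative signs. Those with positive signs were Xlr4a (1.07 ± 0.282), Mterf1b (1.63 ± 0.457), Adam33 (0.96 ± 0.274) and Neu3 (0.68 ± 0.208). Complex I members of smallest p were Ndufab1 (0.47 ± 0.166) and Ndufa12 (0.97 ± 0.433). NF-kB members were Nfkb2 and Rel (−1.05 ± 0.407). Granulocyte members were Olfm4 (−1.33 ± 0.596) and Retnlg (−0.68 ± 0.340). None of these passed.

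No gene passed the threshold in this comparison by edgeR. An unadjusted p under 0.05 was found for 304, where chance gives 750.2. DESeq2 called 3 (Gapdh, Slc15a2 and the immunoglobulin segment Ighv1-5). Leaving out RH VEH 2, the library with 40.8% mitochondrial counts, made 2 genes pass, Gapdh (3.11, adjusted p = 0.000567) and Slc15a2 (4.68, adjusted p = 0.0017, edgeR quasi-likelihood). Then 5 lists were called, 3 of them among the 9. Without WT VEH 3, 4 lists were called, 1 of them among the 9. None of the 9 lists passed in all 12 fits that each left out 1 library. Complex I was lost without WT VEH 3 (camera, adjusted p = 0.0639) or RH VEH 1 (0.0940), the NF-kB list without WT VEH 3 (0.114) and the mitochondrial genome without RH VEH 2 (0.2). Granulocyte and stromal genes were lost without WT VEH 3 or RH VEH 2 (camera, adjusted p up to 0.779 and 0.682), and monocyte genes without WT VEH 1, WT VEH 3 or RH VEH 2 (up to 0.779). Complexes II to V were lost without WT VEH 2, WT VEH 3 or RH VEH 1 (camera, adjusted p up to 0.184). Both ribosome lists were lost without any of WT VEH 2, WT VEH 3, RH VEH 1 and RH VEH 2 (camera, adjusted p up to 0.865).

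RH MET against WT MET gives the difference between the genotypes under the drug. Genes of T and NK cells fell, with 30 of 31 lower and a median log2 fold change of −1.02 (camera, adjusted p = 7.94e-14; adjusted p = 0.723 with an estimated correlation). Immediate early genes, which are switched on within minutes of stimulation, fell with 24 of 26 lower and a median of −0.52 (camera, adjusted p = 1.49e-10; adjusted p = 0.723 with an estimated correlation). Granulocyte genes rose, with 28 of 28 higher and a median of 0.94 (camera, adjusted p = 1.17e-09; adjusted p = 0.767 with an estimated correlation). Their median was 0.66 without WT MET 2, which stood apart with low levels of these genes, and RH VEH 2. Complex I (34 of 36 lower, median −0.40), complexes II to V (34 of 39 lower, median −0.26), the cytosolic ribosome (54 of 54 lower, median −0.39), stem cell genes (32 of 35 lower, median −0.46) and megakaryocyte genes (25 of 27 lower, median −0.47) fell by camera at adjusted p = 1.66e-12 to 0.000124, and at adjusted p = 0.723 to 0.767 with an estimated correlation. WT MET 2 also had high levels of megakaryocyte genes, and without it and RH VEH 2 the medians were −0.25 for megakaryocyte and −0.26 for stem cell genes. These 8 lists passed in all 12 fits that left out 1 library. Those fits share most of their libraries, and fits without a vehicle library kept both groups compared whole. Of 10 splits of the libraries compared, the real one included, 3 gave at least 13 lists, and the others had a median of 11. Passing in all these fits therefore does not exclude chance.

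Slc15a2 rose, at a fitted log2 fold change of 7 ± 0.824 (SE; edgeR quasi-likelihood, adjusted p = 0.0255). With 3 counts in all of WT MET, the fitted value depends on the prior count. The ratio of levels was 125 (95% interval 42.4 to 606, counting error only). Among the immediate early genes, 9 passed when adjusted over the list alone and 0 over all genes. Ier2 (−0.96 ± 0.197) and Junb (−0.75 ± 0.160) were at the front, followed by Nr4a1, Klf2, Egr1, Jun, Egr2, Egr3 and Btg2. Of the T and NK cell genes, 9 passed adjusted over the list alone and 0 over all genes. Among them were the T cell receptor constant gene Trbc1 (−1.81 ± 0.409), the T cell kinase gene Zap70 (−1.62 ± 0.374), the transcription factor genes Tbx21 and Bcl11b, and the cytotoxic granule genes Prf1 and Gzma. Sorted cells were negative for lineage markers. Which cells gave these transcripts, or those of the granulocyte, monocyte and B cell lists, is not known. In the NF-kB list 2 genes passed adjusted over the list alone and 0 over all genes. They were the inhibitor gene Nfkbia (−0.95 ± 0.202) and Traf1 (−1.29 ± 0.353). Further genes of smallest p, none past the threshold over all genes by edgeR, were the dynein gene Dnah8 (1.2 ± 0.208), Gimap6 (−0.82 ± 0.173), the cytokine gene Ifng (−2.04 ± 0.437), Ctla2a (−0.96 ± 0.208) and Myct1 (−0.96 ± 0.212). Stem cell members of smallest p were Pdzk1ip1 (−0.54 ± 0.178) and Hlf (−0.75 ± 0.252). Granulocyte members were Retnlg (0.92 ± 0.342) and Cxcr2 (1.43 ± 0.574).

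Slc15a2 was the 1 gene past the threshold in RH MET against WT MET. An unadjusted p under 0.05 was found for 867 genes, where chance gives 750.2. DESeq2 called 22, among them Slc15a2, Dnah8, Ier2, Junb, Nr4a1, Nfkbia, Ifng, Zap70, Trbc1 and Tbx21. The edgeR call of Slc15a2 was lost without any 1 of WT VEH 1 (adjusted p = 0.0632), WT VEH 2 (0.0633), WT VEH 3 (0.0858), WT MET 1 (0.316), WT MET 2 (0.247), WT MET 3 (0.128), RH MET 2 (0.115) and RH MET 3 (0.487). In these 8 fits its log2 fold change was 6.596 to 10.11, so the calls ended while the fold stayed about as large or became larger. Without RH VEH 1 a further gene, Eps8l1, passed (−3.65, edgeR adjusted p = 0.0447). Of 13 lists called, the remaining 5 were lower and lost their call without 1 or more libraries. This held for dendritic genes (median −0.31) without WT MET 1 (camera, adjusted p = 0.0678), the mitochondrial ribosome (−0.20) without WT MET 3 or RH MET 2 (up to 0.0819) and the mitochondrial genome (−2.08) without WT MET 2 or RH MET 3 (up to 0.582). NF-kB genes (−0.17) were lost without WT MET 1, RH VEH 2 or RH MET 2 (camera, adjusted p up to 0.960), and p53 targets (−0.23) without WT MET 1, WT MET 2, RH VEH 2, RH VEH 3, RH MET 2 or RH MET 3 (up to 0.120). Their adjusted p was 0.767 with an estimated correlation. Without both libraries of high mitochondrial share, 12 of the 13 lists were called in the same direction, all but p53 targets.

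Metformin was next compared with vehicle within the mutant. T and NK cell genes fell in RH MET, with 31 of 31 lower and a median log2 fold change of −0.98 (camera, adjusted p = 7.24e-14; adjusted p = 0.837 with an estimated correlation). Granulocyte genes rose, with 28 of 28 higher and a median of 1.12 (camera, adjusted p = 8.27e-12; adjusted p = 0.837 with an estimated correlation). RH VEH 2 stood apart with low levels of granulocyte genes, and their mean score had an SD of 1.00 in RH VEH against 0.177 in RH MET. Without WT MET 2 and RH VEH 2 the granulocyte median was 0.79, still called by camera. Genes of complex I fell, with 33 of 36 lower and a median of −0.38 (camera, adjusted p = 7.72e-08). So did complexes II to V (35 of 39 lower, median −0.32), the cytosolic ribosome (54 of 54 lower, median −0.33), the mitochondrial ribosome (35 of 42 lower, median −0.28), immediate early genes (23 of 26 lower, median −0.33) and S phase genes (27 of 30 lower, median −0.16). Each of these 6 lists was at adjusted p = 0.837 with an estimated correlation. The complex I score was 0.16 ± 0.397 (SD, n = 3) in RH VEH and −0.194 ± 0.0699 in RH MET. The cytosolic ribosome fell by about as much, so the fall was not particular to complex I. The 8 lists named so far passed in all 12 fits that left out 1 library. This does not exclude chance, as 6 of 10 splits of the libraries compared gave at least 11 lists.

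Within the T and NK list, 8 genes passed when adjusted over the list alone and 0 over all genes. They were the transcription factor genes Tcf7 (−1.15 ± 0.284, SE) and Bcl11b (−1.95 ± 0.499), followed by Zap70, Trbc1, Trac, Trbc2, Lck and Il2rb. Gapdh, at −2.36 ± 0.537, was the 1 glycolysis gene that passed adjusted over the list alone, with 0 over all genes. The other genes of smallest p were Gimap6 (−0.71 ± 0.174), Mpp7 (0.80 ± 0.210), the stress-induced phosphatase regulator gene Ppp1r15a (−0.77 ± 0.202), Mcemp1 (1.21 ± 0.336), Junb (−0.57 ± 0.160), Adgrg7 (1.14 ± 0.326) and Ifng (−1.48 ± 0.433), none past the threshold. Among complex I members, Ndufv2 was at −0.48 ± 0.219. The S phase member was E2f1 (−0.44 ± 0.170), and granulocyte members were Retnlg (1.12 ± 0.344) and Olfm4 (1.59 ± 0.605).

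No gene passed by edgeR in RH MET against RH VEH, with 364 at an unadjusted p under 0.05 (750.2 by chance) and 0 called by DESeq2. Without RH VEH 2, Gapdh passed (−2.79, edgeR adjusted p = 0.0017). Of 11 lists called, the other 3 lost their call without 1 or more libraries. The mitochondrial genome (12 of 12 lower, median −2.41) was lost without RH VEH 2 (camera, adjusted p = 0.604). Erythroid genes (24 of 32 lower, median −0.14) were lost without WT VEH 3, WT MET 2, RH VEH 1, RH VEH 3, RH MET 1 or RH MET 2 (camera, adjusted p up to 0.237). Cholesterol synthesis genes (18 of 24 higher, median 0.12) were lost without WT MET 1, WT MET 2, RH VEH 1, RH VEH 3, RH MET 2 or RH MET 3 (camera, adjusted p up to 0.399). These 3 were at adjusted p = 0.837 with an estimated correlation.

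Metformin against vehicle was then compared in wild-type cells. Whether their animals also held mutant cells is not known, as the labels tie no library to an animal. Megakaryocyte genes rose, with 25 of 27 higher and a median log2 fold change of 0.63 (camera, adjusted p = 2.1e-07; adjusted p = 0.824 with an estimated correlation). Stem cell genes rose, with 29 of 35 higher and a median of 0.50 (camera, adjusted p = 1.21e-05; adjusted p = 0.824 with an estimated correlation). Both lists passed in all 12 fits that left out 1 library. Chance is not excluded by this, as 7 of 10 splits of the libraries compared gave at least 10 lists. Megakaryocyte genes were also higher in the library WT MET 2, with 33.3% mitochondrial counts. The megakaryocyte members of smallest p were the transcription factor gene Fli1 (0.50 ± 0.160, SE) and Cd9 (0.71 ± 0.243). The stem cell members were Nupr1 (0.98 ± 0.343) and Pdzk1ip1 (0.50 ± 0.181), none past the threshold over all genes or adjusted over the list alone. Without both libraries of high mitochondrial share the medians were 0.31 and 0.24, still called by camera (adjusted p = 8.31e-05 and 0.00106; adjusted p = 0.922 with an estimated correlation).

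The other 8 lists called in WT MET against WT VEH each depended on single libraries. Complex I (31 of 36 higher, median 0.27) was lost without WT VEH 2 (camera, adjusted p = 0.0641) or WT VEH 3 (0.0692). Complexes II to V (30 of 39 higher, median 0.20) were lost without WT VEH 2, WT VEH 3 or WT MET 3 (camera, adjusted p up to 0.408), the mitochondrial genome (12 of 12 higher, median 2.18) without WT MET 2 (0.235), and the cytosolic ribosome (52 of 54 higher, median 0.24) without WT VEH 2 (0.0679). The mitochondrial ribosome (36 of 42 higher, median 0.14) was lost without WT VEH 2, WT VEH 3, WT MET 2 or WT MET 3 (camera, adjusted p up to 0.800). Immediate early genes (23 of 26 higher, median 0.26) were lost without WT VEH 1, WT VEH 2, WT MET 1 or WT MET 2 (camera, adjusted p up to 0.529). Glycolysis genes (16 of 21 lower, median −0.15) were lost without WT VEH 1, WT VEH 3, WT MET 1 or WT MET 3 (camera, adjusted p up to 0.250), and granulocyte genes (28 of 28 lower, median −0.51) without WT VEH 3 or WT MET 2 (up to 0.846). All 8 were at adjusted p = 0.824 with an estimated correlation. In round 2 alone the test of the immediate early list pointed down (median 0.03). In round 1 alone the medians of complex I (−0.08), complexes II to V (−0.03), the mitochondrial ribosome (−0.08), the cytosolic ribosome (−0.01) and granulocyte genes (0.17) had the opposite sign.

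Among single genes, Rgs1, a regulator of G protein signalling, was at 0.96 ± 0.172 (SE), and Id1, an inhibitor of DNA-binding transcription factors, at 1.44 ± 0.353. The lipid kinase gene Pik3c2a was at −1.51 ± 0.379, the polyamine acetyltransferase gene Sat1 at 0.52 ± 0.133, Clec2d at 0.87 ± 0.225, Klhl3 at −1.25 ± 0.341, the fatty acid synthase gene Fasn at −0.62 ± 0.171, Lhfp at 1.16 ± 0.325, Tmem245 at −0.60 ± 0.169 and Gsap at 0.99 ± 0.280. None passed by edgeR. In all, 0 genes were called and 604 had an unadjusted p under 0.05 (750.2 by chance). DESeq2 called Rgs1 alone (0.93, adjusted p = 0.0372).

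Whether metformin acted differently in the 2 genotypes was tested directly, as the drug's effect in RH minus that in WT. T and NK cell genes had a lower response in the mutant, with a median difference of −1.11 on the log2 scale (28 of 31 lower; camera, adjusted p = 2.68e-08; adjusted p = 0.779 with an estimated correlation). Complex I was lower by the same measure (median −0.65, 33 of 36 lower), as were complexes II to V (−0.52, 34 of 39), the mitochondrial genome (−4.64, 12 of 12), the cytosolic ribosome (−0.54, 53 of 54), the mitochondrial ribosome (−0.43, 34 of 42), immediate early genes (−0.52, 26 of 26), stem cell genes (−0.62, 31 of 35) and megakaryocyte genes (−0.71, 24 of 27). Granulocyte genes had a higher response in the mutant (median 1.58, 28 of 28 higher), and monocyte genes too (0.39, 20 of 26 higher). The 11 lists passed by camera (adjusted p = 1.61e-10 to 0.0295), and stood at adjusted p = 0.779 to 0.852 with an estimated correlation.

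Members of smallest p were Ndufv2 (−0.98 ± 0.324, SE) and Ndufs4 (−0.67 ± 0.232) of complex I, Cox6c (−1.01 ± 0.304) and Atp5l (−0.76 ± 0.241) of the other complexes, and Ier2 (−0.92 ± 0.284) and Klf2 (−0.74 ± 0.253) of the immediate early genes. Also named by the rule were the platelet factor gene Pf4 (−1.83 ± 0.642), Bcl11b (−2.26 ± 0.696) and Zap70 (−1.71 ± 0.531) of the T and NK genes, and Retnlg (1.61 ± 0.484) of the granulocyte genes. The genes of smallest p overall were the ribosomal protein gene Rps12 (−1.44 ± 0.344), Xlr4a (−1.62 ± 0.410), Adgrg7 (1.71 ± 0.460), Cd300lf (2.19 ± 0.591), Tmem245 (0.89 ± 0.247) and the RNA polymerase subunit gene Polr2h (−1.27 ± 0.356). They were followed by Gapdh (−2.92 ± 0.762), Fasn (0.89 ± 0.253), Dnah8 (1.05 ± 0.302) and Adam33 (−1.38 ± 0.40). None passed over all genes or adjusted over a list alone. The 2 libraries of high mitochondrial share, WT MET 2 and RH VEH 2, stand on the same side of this difference. Without them 10 of the 11 lists were called in the same direction, with medians of −0.45 for complex I, −0.98 for the mitochondrial genome, 0.91 for granulocyte genes and −1.30 for T and NK genes. The monocyte median turned to −0.05.

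No gene passed by edgeR in this difference, with 932 at an unadjusted p under 0.05 (750.2 by chance) and 0 called by DESeq2. Without RH VEH 2, Gapdh passed (−3.24, edgeR adjusted p = 0.0118). All lists but 1 passed in the 12 fits that left out 1 library, but 40 of 60 splits of the libraries gave at least 11 lists. Monocyte genes were lost without WT VEH 1, WT VEH 3, WT MET 2, RH VEH 2 or RH MET 3 (camera, adjusted p = 0.127 to 0.653).

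**Figure D3:**
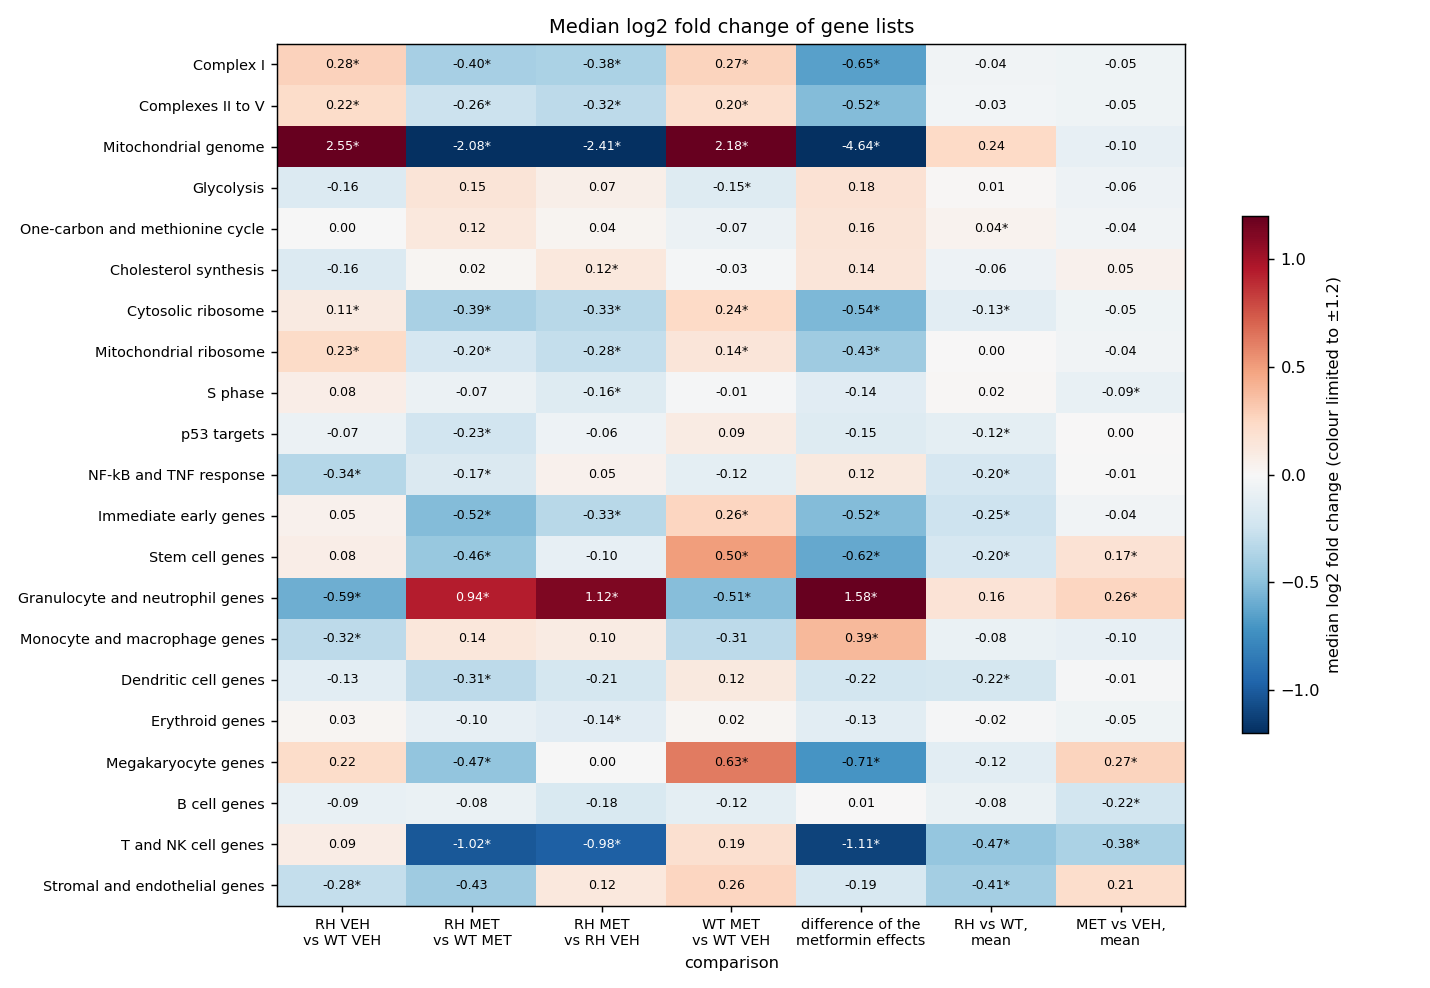
Median log2 fold change (colour and number, colour limited to 1.2 either way) of the 21 gene lists called in any comparison (y axis) in the 7 comparisons (x axis); an asterisk marks an adjusted p under 0.05 by camera with the preset correlation, and none passes with an estimated correlation. Complex I is at 0.28 for RH against WT under vehicle and −0.40 under metformin, and T and NK cell genes at 0.09 and −1.02.

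**Figure D4:**
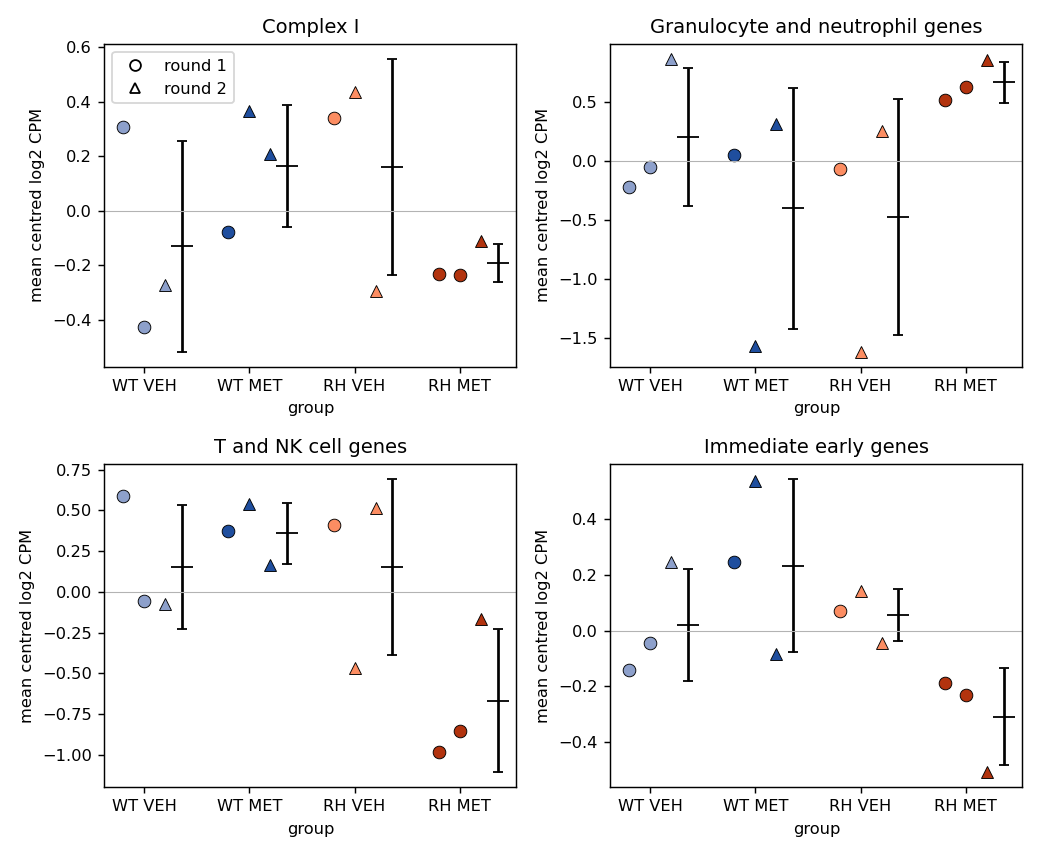
Mean centred log2 CPM (y axes) of complex I, granulocyte, T and NK cell and immediate early genes in each of the 12 libraries by group (x axes); circles are round 1, triangles round 2, and bars the group mean ± SD (n = 3). RH MET libraries average −0.19 ± 0.0699 for complex I, 0.67 ± 0.177 for granulocyte genes, −0.67 ± 0.439 for T and NK genes and −0.31 ± 0.173 for immediate early genes. Other groups spread wider for the first 2 lists. Complex I averages −0.132 ± 0.387 in WT VEH, 0.165 ± 0.224 in WT MET and 0.16 ± 0.397 in RH VEH. Granulocyte genes average 0.202 ± 0.585, −0.398 ± 1.02 and −0.477 ± 1 in the same order.

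The mean genotype effect averages RH against WT over both treatments. Immediate early genes fell, with 20 of 26 lower and a median log2 fold change of −0.25 (camera, adjusted p = 2.32e-07; adjusted p = 0.571 with an estimated correlation). NF-kB and TNF response genes fell, with 24 of 28 lower and a median of −0.20 (camera, adjusted p = 4.74e-07; adjusted p = 0.571 with an estimated correlation). T and NK cell genes fell, with 28 of 31 lower and a median of −0.47 (camera, adjusted p = 2.58e-10; adjusted p = 0.571 with an estimated correlation). Under vehicle alone immediate early genes (median 0.05) and T and NK cell genes (0.09) were not lower and not called, so their mean effect came from the comparison under metformin (−0.52 and −1.02). NF-kB and TNF response genes were at −0.34 under vehicle and −0.17 under metformin. These 3 lists passed in all 12 fits that left out 1 library and without both libraries of high mitochondrial share. Chance is still open, as 50 of 60 splits of the libraries gave at least 9 lists. Slc15a2 rose, at 5.66 ± 0.514 (SE; edgeR quasi-likelihood, adjusted p = 0.00149), in all 12 fits that left out 1 library (adjusted p = 1.61e-05 to 0.0207). The call ended in limma voom with a correlation within assumed animals (5.71, adjusted p = 0.366) and in round 2 alone (5.55, edgeR adjusted p = 1), with the fold about unchanged in both.

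Adjusted over the list alone, 3 immediate early genes passed (Nr4a1 at −0.92 ± 0.180, Junb at −0.47 ± 0.110 and Ier2), 2 NF-kB genes (Nfkbia at −0.67 ± 0.139 and Nfkb2 at −0.55 ± 0.141), 1 interferon response gene (Irf1 at −0.59 ± 0.132) and 1 T and NK gene (Tbx21 at −1.37 ± 0.326), each list with 0 over all genes. Other genes of smallest p, not past the threshold by edgeR, were Zbtb10 (−1.14 ± 0.20), Clec2f (1.27 ± 0.260), Dnah8 (0.67 ± 0.143), Myct1 (−0.69 ± 0.146), Snx31 (0.80 ± 0.175) and the transcription factor gene Bhlhe40 (−0.95 ± 0.211). Further lists called were stromal and endothelial genes (23 of 24 lower, median −0.41), lost without RH VEH 2 (camera, adjusted p = 0.103), and stem cell genes (25 of 35 lower, −0.20), lost without WT MET 2 (0.165). So were dendritic genes (17 of 19 lower, −0.22), lost without WT VEH 1 or RH VEH 2 (camera, adjusted p up to 0.307), and p53 targets (16 of 21 lower, −0.12), lost without WT MET 2, RH VEH 3 or RH MET 2 (up to 0.177). The last 2 were the cytosolic ribosome (53 of 54 lower, −0.13), lost without WT VEH 1 or RH VEH 3 (camera, adjusted p up to 0.632), and the one-carbon and methionine cycle (20 of 28 higher, 0.04), with Mat2a at 0.32 ± 0.103, lost without WT VEH 2, WT MET 2, RH VEH 2, RH VEH 3 or RH MET 1 (up to 0.201). These 6 were at adjusted p = 0.571 to 0.965 with an estimated correlation. Among them the cytosolic ribosome and stem cell lists went opposite ways under the 2 treatments. Ribosome scores were −0.0667 in WT VEH and 0.0953 in RH VEH, but 0.194 in WT MET and −0.222 in RH MET. Stem cell scores were −0.116 and −0.0487 under vehicle, but 0.319 and −0.154 under metformin.

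For this mean effect 1 gene passed by edgeR and 397 had an unadjusted p under 0.05 (750.2 by chance). DESeq2 called 17, among them Slc15a2, Zbtb10, Nr4a1, Nfkbia, Clec2f, Snx31, Myct1, Bhlhe40, Dnah8 and Irf1. A second gene passed by edgeR without RH VEH 1 (Eps8l1, −3.32, adjusted p = 0.00968), without RH VEH 2 (Gapdh, 1.49, adjusted p = 0.0154) and without RH VEH 3 (Smoc1, −4.19, adjusted p = 0.0234).

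The mean effect of metformin over both genotypes came next. T and NK cell genes fell, with 29 of 31 lower and a median log2 fold change of −0.38 (camera, adjusted p = 4.67e-07), and S phase genes fell, with 27 of 30 lower and a median of −0.09 (camera, adjusted p = 0.000145). Both were at adjusted p = 0.95 with an estimated correlation. Both passed in all 12 fits that left out 1 library, although in round 2 alone their medians were 0.09 and 0.02. In 54 of 60 splits of the libraries at least 6 lists were called, so chance is not excluded. The fall of T and NK cell genes came from RH. Their mean score was 0.153 in RH VEH and −0.666 in RH MET, but 0.153 in WT VEH and 0.359 in WT MET. Megakaryocyte genes (24 of 27 higher, median 0.27), stem cell genes (26 of 35 higher, 0.17) and granulocyte genes (25 of 28 higher, 0.26) rose and B cell genes (20 of 25 lower, −0.22) fell by camera at adjusted p = 3.21e-05 to 0.0221, and at adjusted p = 0.95 to 0.967 with an estimated correlation. These 4 calls were lost without WT MET 2 or RH VEH 1 for megakaryocyte genes (camera, adjusted p up to 0.201) and without WT VEH 1, WT MET 2 or RH VEH 3 for stem cell genes (up to 0.335). The same held without WT VEH 1, WT VEH 2, WT MET 1, WT MET 3, RH VEH 2 or RH MET 3 for granulocyte genes (camera, adjusted p up to 0.731), and without WT VEH 1, WT MET 3, RH VEH 3 or RH MET 2 for B cell genes (up to 0.346). Without RH VEH 2 the test of the granulocyte list pointed down, and its median ran from 0.05 to 0.53 over the 12 fits. For the lists that rose, the genotypes went opposite ways from vehicle to metformin. Megakaryocyte scores went from −0.208 to 0.338 in WT and from −0.0372 to −0.0926 in RH. Stem cell scores went from −0.116 to 0.319 in WT and from −0.0487 to −0.154 in RH. Granulocyte scores went from 0.202 to −0.398 in WT and from −0.477 to 0.67 in RH.

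Single genes of smallest p were Rgs1 (0.57 ± 0.120, SE), Sat1 (0.41 ± 0.0922), the microRNA host gene Mir17hg (0.52 ± 0.121), Id1 (1.02 ± 0.245), Tcf7 (−0.72 ± 0.193) and Clec2d (0.53 ± 0.154). Next came the cytokine gene Il6 (0.63 ± 0.184), the stearoyl-CoA desaturase genes Scd1 (−0.65 ± 0.20) and Scd2 (−0.42 ± 0.125), and Nr4a1 (−0.60 ± 0.179). No gene passed by edgeR. Of the 15003, 244 had an unadjusted p under 0.05 (750.2 by chance), and DESeq2 called 0. The count of 6 lists became 12 without WT VEH 2, 14 without WT VEH 3, 12 without RH VEH 3, 11 without RH MET 3 and 4 without WT VEH 1.

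The remaining 13 lists were called in none of the 7 comparisons, with medians between −0.33 and 0.31 and a smallest adjusted p of 0.0512 by camera. For metformin in the mutant their medians were −0.04 for TCA cycle genes, 0.09 for the DNA methylation machinery, −0.05 for PRC2, 0.06 for homeobox and Meis genes, 0.03 for the ATF4 stress response and −0.03 for fatty acid oxidation. They were −0.02 for mitosis, 0.10 for interferon response, 0.06 for hypoxia, −0.05 for NRF2 targets, −0.02 for lysosome genes, 0.05 for multipotent progenitor genes and 0.10 for mast cell genes.

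Genome-wide, the genotype effect under vehicle and that under metformin had a negative correlation across the 15003 genes (r = −0.224, rho = −0.308; covariance −0.0569). Simulated unchanged groups gave a mean r of −0.0539 and covariance of −0.0117. The metformin effects in RH and in WT had one too (r = −0.326, rho = −0.362; covariance −0.0769; simulated −0.0554 and −0.0120). The genotype effect under vehicle and the metformin effect in RH share the RH VEH libraries and gave r = −0.655, rho = −0.618 and covariance −0.152. The simulation gave −0.538 and −0.116. Genes are not independent replicates. The simulated genes were drawn independently, so the simulation lacks variation that the genes of a library share and does not measure chance. Other splits of the libraries gave r of −0.569 to 0.527, −0.553 to 0.495 and −0.852 to 0.2 in this order. Without both libraries of high mitochondrial share the 3 values of r were −0.00767, −0.0783 and −0.560. With an added round level for them the values were 0.0128, −0.101 and −0.534, and in round 1 alone −0.0402, −0.0458 and −0.731, so opposite genotype effects under the 2 treatments are not established. Among genes of mean log2 CPM of at least 3 the first 2 values of r were stronger, at −0.557 and −0.617. The first 2 moved by over 1.5 times when single libraries were left out. The first went to −0.0709 without WT MET 2, −0.0551 without RH VEH 2, −0.145 without WT VEH 3 and −0.355 without WT MET 1, and the second went to −0.145 without WT MET 2 and −0.139 without RH VEH 2.

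Overlaps of genes at an unadjusted p under 0.05 are set beside the number that independent lists give. Of the genes lower in RH, 21 were shared between vehicle and metformin (4.92 for independent lists), and of those higher, 7 (3.65). Genes higher under vehicle and lower under metformin numbered 8 (6), and the reverse 4 (3). The genes of smallest p thus overlapped more in the same direction than in opposite ones, unlike the sign of r over all genes. Both comparisons come from the same fit, and the benchmark takes genes as independent. No other splits of the libraries were run for the overlaps, so how many shared genes chance gives is not known. Genes lower with metformin in RH and higher with it in WT numbered 18 (4.79), and genes lower in both numbered 1 (4.39). Genes higher with metformin in both genotypes numbered 5 (2.86), and genes higher in RH and lower in WT 4 (2.62), so these 2 counts show no preference for opposite directions.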

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

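The comparison of the metformin effects of the 2 genotypes was planned; the tests that weigh explanations in this part, and the counts of other splits, were chosen only after the result was seen.

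For 11 gene lists the metformin effect differed between the genotypes, by a test of the difference itself, the effect in RH minus the effect in WT (camera with the preset correlation, n = 3 libraries per group). The median differences on the log2 scale were −0.651 for complex I, −0.518 for complexes II to V, −4.64 for the mitochondrial genome, −0.538 for the cytosolic ribosome, −0.427 for the mitochondrial ribosome, −0.520 for immediate early genes, −0.615 for stem cell genes, 1.58 for granulocyte genes, 0.386 for monocyte genes, −0.711 for megakaryocyte genes and −1.11 for T and NK cell genes. With an estimated correlation none passed (adjusted p = 0.779 to 0.852), so the calls rest on the preset correlation between genes.

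The pattern was weighed against 3 technical explanations. If the libraries of high mitochondrial share, WT MET 2 and RH VEH 2, had made the whole pattern, it would end without them. Without them 10 of the 11 lists were called in the same direction. Complex I was then at −0.45, the mitochondrial genome at −0.98 and T and NK genes at −1.30, while monocyte genes turned to −0.05. The granulocyte difference became smaller. The calls thus did not rest on these 2 libraries alone, but several sizes did in part. Other splits of the libraries gave a median of 12 called lists, so a kept call does not show its cause. If a single round of libraries had made it, the other round would not show it; 9 of the 11 lists were called in the same direction in each round alone, but in each round 2 of the 4 groups held 1 library, so this stays open. Chance stays open: 40 of 60 splits of the 12 libraries gave at least 11 lists (highest other 19), so chance cannot be excluded. That metformin acts on these gene groups differently in mutant and wild-type cells may be put forward only as a hypothesis, and it stays open.

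For single genes in the same difference, 17 of 60 splits gave as many genes at an unadjusted p under 0.05 as the real 932, with 4238 in the highest other split, so chance cannot be excluded. Splits that call several times the real count point to a structure of the samples. In the real split WT MET 2 and RH VEH 2 are on the same side of the difference; 15 of the 27 other splits that also place them so gave at least 932 genes (median 1201), against 1 of the 32 that place them on opposite sides (median 257).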

How the results depend on the processing

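Depth and the 3 libraries per group set limits: a gene below 1 CPM had few counts, and 2-fold changes in single comparisons were often missed on simulated counts. Spread between libraries set limits too, with a biological coefficient of variation of 0.256, or 0.18 without WT MET 2 and RH VEH 2. The alternatives without the 2 libraries of high mitochondrial share (WT MET 2 and RH VEH 2) and with an added round level for them were chosen after seeing the data. Where no reason is given, the cause was not tested.

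Counts of genes past the threshold, in the order RH against WT under vehicle and under metformin, metformin in RH and in WT, difference, mean genotype and mean metformin, were 0, 1, 0, 0, 0, 1 and 0. With no filter they were 175, 362, 229, 218, 431, 119 and 63 of 27530 genes, of which 168, 349, 220, 210, 412, 118 and 63 were among the 15003 genes of the filter, so few of them were genes that the filter removes; the cause was not tested. DESeq2 gave 3, 22, 0, 1, 0, 17 and 0. In RH against WT under metformin the count fell from 1 to 0 with no round term, with only the groups compared, in round 1 or round 2 alone and in limma voom with a correlation within assumed animals (libraries of the same treatment and label number; consensus −0.117); the voom fit and round 2 alone also gave 0 for mean genotype. Round 1 alone gave 2 under vehicle (Gapdh and mt-Atp6), 3 for metformin in RH, 3 for the difference, 2 for mean genotype and 2 for mean metformin. Without the 2 libraries the counts were 3 under vehicle, 1 for metformin in RH, 1 for the difference and 3 for mean genotype; with the added level they were 1 under vehicle and 2 for mean genotype. Leaving out each library gave 0 to 2 under vehicle, 0 to 2 under metformin, 0 to 1 for metformin in RH, 0 to 1 for the difference and 1 to 2 for mean genotype.

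Counts of lists were 9, 13, 11, 10, 11, 9 and 6 in the same order. They were 0 in all 7 comparisons with an estimated correlation and 0 in all 7 by fry. Round 2 alone gave 15 under vehicle, round 1 alone 11 for mean metformin, and leaving out each library 4 to 11 under vehicle and 4 to 14 for mean metformin. Medians of called lists that changed sign in round 1 alone were, under vehicle, granulocyte 0.0055 and monocyte 0.125; for metformin in WT, complex I −0.081, complexes II to V −0.025, cytosolic ribosome −0.0139 (its test still pointed up), mitochondrial ribosome −0.075 and granulocyte 0.167; and for the difference, monocyte −0.00371. In round 2 alone they were, for metformin in RH, erythroid 0.0786, and for mean metformin, S phase 0.0155 and T and NK 0.0918; the immediate early list for metformin in WT had a median of 0.0251 while its test pointed down. Monocyte genes were at 0.0465 under vehicle and −0.0502 in the difference without the 2 libraries, and at −0.0645 in the difference with the added level. Leaving out each library moved the NF-kB median under metformin between −0.298 and 0.0289, the monocyte median under vehicle between −0.833 and 0.0639, and the granulocyte median for mean metformin between 0.0522 and 0.527, where its test pointed down without RH VEH 2.

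Dnmt3a, called in no comparison, changed sign for metformin in WT with no round term (0.0206), in round 2 alone for mean genotype (−0.0865) and mean metformin (−0.0607), and without the 2 libraries for mean metformin (−0.0751). Leaving out each library gave −0.051 to 0.0743 for mean genotype and −0.03003 to 0.104 for mean metformin. Shares of counts differed by sign in round 1 alone, in percentage points, for haemoglobin under vehicle (0.0728) and for metformin in WT (−0.0424), and for ribosomal proteins under vehicle (0.655) and for metformin in RH (−1.60). In round 2 alone haemoglobin for metformin in RH was at 0.167. Without the 2 libraries haemoglobin was at 0.0418 under vehicle, and ribosomal proteins at 0.0159 under vehicle and −0.594 for metformin in RH. Under metformin, RH against WT, ribosomal proteins went from −0.583 to −1.32 (exact permutation p = 0.1, the smallest possible).

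Correlations across genes, in the order of the 2 genotype effects, the 2 metformin effects, and genotype under vehicle against metformin in RH, were −0.224, −0.326 and −0.655. Genes of mean log2 CPM of at least 3 gave −0.557 and −0.617 for the first 2, the filter of 1 CPM in 6 libraries −0.317 and −0.435, no filter −0.0657 and −0.0833, and round 1 alone −0.0402 and −0.0458. Without the 2 libraries they were −0.00767, −0.0783 and −0.560, and with the added level 0.0128, −0.101 and −0.534. Leaving out each library gave −0.355 to −0.0551, −0.421 to −0.139 and −0.842 to −0.528.

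The label number as a replicate block, where the column carries it (1, 2, and 1 level for the round 2 libraries), gave 9, 13, 12, 14, 11, 10 and 7 lists and the same counts of genes. Whether the numbers pair libraries could not be decided. Same-numbered pairs had residual correlations of −0.31 to 0.0128 over 6 pairs, and other pairs −0.291 to 0.0288 over 7. Of the same-numbered pairs only WT VEH 2 with RH VEH 1 (−0.31) and WT MET 1 with RH MET 1 (−0.14) share a treatment. The group and round means of the fit also tie the residuals together. DESeq2 size factors within edgeR moved no count by over 1.5 times.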

Other observations

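The tests of the mitochondrial share and of Slc15a2 in this part, the gene counts without overlap and the counts of splits for genes and lists were chosen only after the result was seen; what the splits for the correlations would show was set out before those splits were run, but after the correlations themselves were seen.

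Apart from Slc15a2, few genes kept all RH libraries on one side of all WT libraries. Of the 15003 genes tested, 14 separated the genotypes without overlap, 3 higher in RH (Slc15a2, Clec2f and Snx31) and 11 lower, where chance gives 32.5 (0.216%). The lower ones included the T cell transcription factor gene Tbx21, at 0.647 to 2.12 CPM in RH and 2.13 to 6.09 in WT, the phosphatase gene Dusp4, at 1.39 to 1.91 and 2.04 to 3.48, the ion channel gene Trpc1, at 0 to 0.344 and 0.441 to 1.93, and Myct1, at 10.3 to 15.9 and 15.9 to 26.3. Metformin against vehicle gave 11 genes without overlap, 10 higher and 1 lower, where chance again gives 32.5.

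A few genes were high or low in single libraries of a group, and were chosen here after their values were seen. Eps8l1 stood at 5.85 to 18.2 CPM in the 6 WT libraries and at 0.324 to 1.67 CPM in 5 of the 6 RH libraries, but at 11.7 CPM in RH VEH 1. Gapdh stood at 172 CPM in RH VEH 1 and 68.1 in RH VEH 3, and at 13.2 to 21 in the other 10 libraries.

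The share of mitochondrial counts in WT MET 2 (33.3%) and RH VEH 2 (40.8%) was weighed against 3 explanations. Treatment or genotype does not account for it by itself, since the other libraries of the same groups reached at most 4.325%. Damaged cells that had lost cytoplasmic RNA, a candidate explanation, would raise RNAs kept in the nucleus, but the median log2 difference of 10 such RNAs was 0.212, with Neat1 at 1.17 and Kcnq1ot1 at 1.39 beside Malat1 at −0.113, so this stays open. A handling step shared by the 2 libraries stays open too, as their residuals without mitochondrial genes correlated at 0.340, inside the range of other pairs between groups (−0.495 to 0.465).

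For Slc15a2 in RH cells, weighed in the same way, a change of the whole surrounding region is argued against by the 22 tested genes within 1 Mb, with a median log2 fold change of 0.0547 and none past the threshold. The 11 cell type lists had a highest median of 0.165, so none of these lists rose as a whole with Slc15a2. A list median can miss a small subset of cells, so cells of another type stay open. At least 1 gene passed the threshold in 9 of 60 splits of the 12 libraries (1 gene in the real one, highest other 1972), so by this count chance cannot be excluded; Slc15a2 itself passed in 1 of the 60, the real one, but it was picked for passing there. All 462 splits of 6 against 6 libraries and all 15003 genes were then taken, which allows for the choice of gene. In 2 splits, the real one included, some gene was parted by at least the gap of Slc15a2 (2.51 in log2 CPM). The other split reached 2.69. Such a gap was thus rare among the splits. The measure was itself chosen after the separation was seen, and libraries that share an animal cannot be swapped freely, so chance is not excluded. A variant or a passenger segment that differs between the mouse lines, and an effect of the mutation itself, were not tested and stay open; that the R878H change raises Slc15a2 is thus only a hypothesis.

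With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. At an unadjusted p under 0.05, RH against WT under vehicle gave 304 genes with 5 of 10 splits as large (highest other 4428), metformin in RH 364 with 5 of 10 (1292) and metformin in WT 604 with 4 of 10 (1475); past the threshold, RH against WT under metformin gave 1 with 1 of 10 (highest other 0). The 4428 genes of another split under vehicle point to a structure of the samples. Lists numbered 9 under vehicle with 9 of 10 splits as large (highest other 17), 13 under metformin with 3 of 10 (16), 11 for metformin in RH with 6 of 10 (14) and 10 for metformin in WT with 7 of 10 (18).

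Over all 12 libraries 60 splits were drawn, the real one included. Mean genotype gave 1 gene past the threshold with 9 of 60 splits as large (highest other 1972) and 9 lists with 50 of 60 (highest other 18), and mean metformin gave 244 genes at an unadjusted p under 0.05 with 41 of 60 (4085) and 6 lists with 54 of 60 (19), so chance cannot be excluded for these counts. Splits that call several times the real count of genes point to a structure of the samples: in the real genotype and metformin splits WT MET 2 and RH VEH 2 are on opposite sides, and the splits with the most genes (1972 and 4085) place them on the same side. Of the 28 other splits with them on opposite sides, 2 gave a gene past the threshold for genotype (1 at most), 21 gave at least 9 lists, and for metformin 16 gave at least 244 genes and 22 at least 6 lists, so chance cannot be excluded among these either. The correlations were −0.224 between the genotype effects, −0.326 between the metformin effects and −0.655 between genotype under vehicle and metformin in RH; 7, 3 and 8 of 60 splits were as low (lowest others −0.569, −0.553 and −0.852), so chance cannot be excluded for them either.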
